A study of Mus musculus with 13 samples.

How the data were processed

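RNA was measured in 13 libraries of cells sorted by flow cytometry from tissue around tibia implants of mice. The sort took lineage-negative cells that carried the leptin receptor on their surface, a marker of stromal cells of the marrow. Per the labels, 7 libraries came from fibrous tissue around implants named PMMA and 6 from bone around implants named Pressfit. The labels' protocols give polyA RNA, an RNeasy Plus Micro kit for RNA extraction, Illumina TruSeq libraries and a NovaSeq sequencer.

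The values analysed are raw counts per gene, as deposited by the authors in one matrix for the whole series. The authors' counts were whole numbers for 23211 mouse Ensembl gene IDs, and every gene in the matrix had at least 1 count over the 13 libraries. The submitters' processing notes name edgeR, with no version, and the builds mm10 and hg38, with no role for either. The aligner, the counting tool, the annotation release and whether strand was used are not given in the sources used here. All 23211 IDs matched a symbol, and coordinates were taken from GENCODE mouse release M21, which describes the mm10 assembly. No mitochondrially encoded gene was among the IDs, so their share of the RNA is not analysed here.

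Library names fell into 2 series. The L002 series held 9 libraries (4 bone, 5 fibrous) and the XY9274 series held 4 (2 bone, 2 fibrous). In the L002 series, 3 library names held the token Lin (2 bone, 1 fibrous) and the other names did not. Of those other L002 names, all but that of fibrous 1 held the token plus. Replicate numbers were given in accession order, so they name libraries and pair none. Bone 2 and bone 4 shared one name token, as did fibrous 2 and fibrous 5. In both pairs the first name held plus and the second Lin. The labels do not say whether libraries came from separate animals, or whether such a pair came from one sample. The p-values therefore measure only the spread between these libraries, which may be technical.

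The groups, the tests, the gene lists, the rule for named genes and a set of alternative settings were fixed before the data were examined. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr on the groups, robust dispersions and the quasi-likelihood F test, with name series and group as terms. It tested 13294 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) is the log2 fold change divided by the square root of the F statistic. Log2 fold changes are fibrous minus bone, and for genes close to 0 counts in one group they depend on the prior count of the fit, so normalised CPM are given for those, alone or beside the fold change. The same test was run within each name series, for the interaction of series and group, and for the difference between series. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights) were alternative tools. Normalised CPM are edgeR's CPM with the library size scaled by its TMM factor.

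A total of 39 gene lists were fixed, of stromal programmes, signalling, general cell functions and cell types that the sort could have carried over. The 36 lists with at least 3 tested members were tested with camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01. Camera, which compares a list with the other genes, was repeated with an estimated correlation. Fry, which asks whether the list itself changed, was run beside it. A list score is the mean log2 CPM of its tested members. The adhesion GPCR list and Adgrf5 were chosen from memory of the study behind the series, so neither is independent evidence.

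Genes were named by the following rule. Lepr, as the sort marker, and Adgrf5 came first. Next came the 12 genes with the largest positive and the 12 with the largest negative fold change past the threshold, with a mean of at least 5 CPM in the higher group and the same sign in both series, leaving out symbols of the form Gm plus digits or ending in Rik. Where fewer passed, the smallest p-values in that direction filled the places, named as not past the threshold. Last came up to 4 members of each programme list and up to 3 of each cell type list, by smallest p. The rule for the fill did not say whether the expression and sign conditions applied to it, and they were applied after the data had been seen. The text describes a subset of the list members, and 98 of the 158 genes named by the rule were recomputed under each alternative. Cxcl12, Col1a1, Col2a1, Ngp and the genes of the name series comparison were chosen after their values were seen.

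For 10 measures (Lepr, Adgrf5, 3 composition shares, 4 list scores and the number of genes detected), 2-sided exact permutation tests over 1716 splits (genes and shares on the log2 scale, genes with a pseudocount of 1), and over 756 splits within series, and again with each library left out, were added after seeing the data. The settings added at that stage were leaving out 5 libraries with Lepr under 5 normalised CPM, list scores or the Lepr level as covariates, leaving out erythroid genes, and the alternative tools for the series fits. The test of the lists between series was also added after seeing the data. Settings fixed earlier covered the series term, a 3-level name factor, the Lin-named libraries, summing libraries that share a token, the tools, size factors, the filters, each library in turn and a minimum fold. The 3-level factor set Lin names, other L002 names and XY9274 names apart, so fibrous 1 was grouped with the plus names.

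The depth ran from 16162321 to 44302166 counts per library. A limit of 3 counts, the most that a count of 0 allows, stood at 0.0564 to 0.301 normalised CPM, and covers counting error only. Reads of near-identical genes, such as Hspa1a and Hspa1b or the haemoglobin genes, and of overlapping genes may be divided between them in ways that the counts do not show. No 2 libraries agreed within sampling noise: the closest pair had a chi-square of 89.8 per degree of freedom over genes with at least 20 counts in the pair. Fits were tested on simulated data, 4 sets of 13294 genes with 200 genes changed in each. For the comparison of all 13 libraries, edgeR called 6.50% of genes changed 2-fold, 35.5% at 4-fold, 50.5% at 8-fold and 62.0% at 16-fold, and 13 unchanged genes over the 4 sets. DESeq2 called 22.0%, 53.5%, 70.5% and 82.5%, and 264 unchanged genes. limma-voom called 5.50%, 35.0%, 46.0% and 55.0%, and 17 unchanged genes. With the osteoblast list changed 2-fold, camera called it in 4 of 4 sets with either correlation and called 0 other lists in those sets. Genes were drawn independently in the simulated sets, while the median correlation estimated within the real lists was 0.488. The simulated list result therefore does not show how often either form of the test errs on correlated lists.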

Results

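By its labels, the series profiled leptin receptor positive, lineage-negative stromal cells sorted from fibrous tissue or from bone around tibia implants of mice. Totals ran from 16162321 to 43217004 counts over the 6 bone libraries and from 18056208 to 44302166 over the 7 fibrous libraries, and between 14644 and 20146 genes were detected per library. The design text names one comparison, fibrous against bone, and the library names add a second division into the L002 and XY9274 series.

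Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, plus strand), the gene of the sort marker, varied widely within both groups. Its normalised CPM was 46.7, 143, 0.644, 0.602, 2.42 and 102 in bone 1 to 6. In fibrous 1 to 7 it was 0.469, 804, 407, 197, 0.739, 67.2 and 60.3. Thus 5 libraries, bone 3, 4 and 5 and fibrous 1 and 5, lay under 5 CPM, among them all 3 libraries with Lin in their name. Cxcl12, a chemokine that marrow stromal cells secrete in large amounts, lay between 5.48 and 32.7 CPM in those libraries and between 376 and 7965 CPM in the others. In both pairs that share a name token, Lepr was high in the plus and near 0 in the Lin library. It was at 143 in bone 2 and 0.602 in bone 4, and at 804 in fibrous 2 and 0.739 CPM in fibrous 5. The Lepr log2 fold change of fibrous over bone was 1.88 (SE 1.67, n = 7 and 6; adjusted p = 0.891), and the 2-sided exact permutation p was 0.330 (adjusted p = 0.369 over 10 measures). Within the L002 series it was 2.55 and within XY9274 0.24, and with erythroid and pan-leukocyte scores as covariates -0.27.

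Transcripts of other cell types took very different shares of the libraries. Haemoglobin genes made up 0.128% of the counts in bone 5 and 35.3% in bone 4, with 27.9% in bone 3 and 19.97% in fibrous 5. The neutrophil list, granule and calprotectin genes, held 9.99% of the counts in bone 5, where Ngp, a granule protein gene of neutrophil precursors, was the most abundant gene. Immunoglobulin genes held 3.18% there and at most 0.3598% in any other library. Mean shares in bone and fibrous libraries were 13.4% ± 14.5 and 7.14% ± 6.86 (SD) for haemoglobin (exact permutation p = 0.858, adjusted p = 0.858). For the neutrophil list they were 3.26% ± 3.52 and 0.919% ± 0.919 (exact permutation p = 0.120, adjusted p = 0.240). Col2a1, the main cartilage collagen, was the top gene of bone 1, fibrous 6 and fibrous 7, at 32024, 15200 and 38370 CPM.

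**Figure D1:**
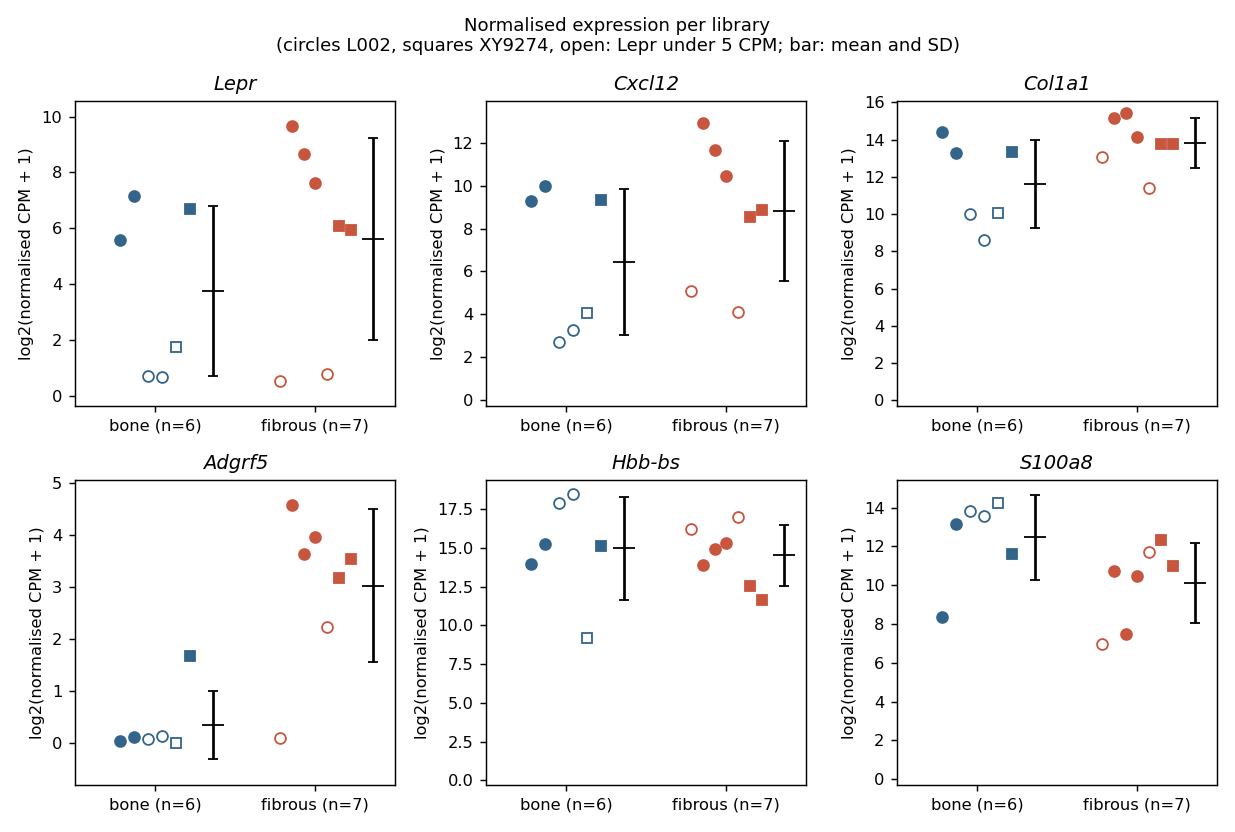
Normalised expression of 6 genes, as log2(CPM + 1) on the y axis, for the 6 bone and 7 fibrous libraries on the x axis. Circles are L002 and squares XY9274 libraries, open symbols have Lepr under 5 CPM, and the bar gives the group mean with its SD. Lepr and Cxcl12 split both groups into low and high libraries, and Adgrf5 is at or below 2.20 CPM in all bone libraries.

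The comparison of fibrous with bone tissue asked how the sorted cells differ between the 2 kinds of peri-implant tissue. Lists of collagen matrix, bone formation and stromal genes had higher values in the fibrous libraries, and neutrophil, leukocyte and ribosomal lists lower values, by camera with a preset correlation. With an estimated correlation 0 of the 36 lists passed (smallest adjusted p = 0.556), and 0 passed by fry. Bone 3 and bone 4, with haemoglobin at 27.9% and 35.3% of their counts, had the 2 lowest scores of the marrow stromal, fibrillar matrix, osteoblast and osteocyte lists. Mrc2, an endocytic collagen receptor, was at 33.4 ± 21.04 CPM (SD, n = 7) in fibrous and 2.85 ± 4.64 CPM (n = 6) in bone libraries (log2 fold change 6.46, SE 1.37). Lamb1, a laminin chain of basement membranes, was at 29.1 ± 24.0 against 1.85 ± 2.65 CPM (log2 fold change 5.38, SE 1.29). S100a8, a calprotectin subunit of neutrophils, was at 2006 ± 1797 against 9830 ± 7153 CPM (log2 fold change -2.41, SE 0.89). None of the 13294 genes passed 0.05 by edgeR (smallest adjusted p = 0.873), with 636 at an unadjusted p under 0.05 where 664.7 are expected by chance. DESeq2 called 169 genes, 148 higher and 21 lower in fibrous libraries, and limma-voom called 0 with 1151 at an unadjusted p under 0.05. The common biological coefficient of variation was 0.904.

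Because no gene passed, the named genes have the smallest p-values in each direction among genes that met the expression, sign and symbol conditions. Genes outside these conditions were left out whatever their p-value, and the shared sign in both series was a condition of the choice. None of the named genes is past the threshold (adjusted p = 0.873 by edgeR for each). With higher values in fibrous libraries, Dst (chromosome 1, 33908225 to 34308661), a linker of the cytoskeleton to adhesion sites, had a log2 fold change of 2.91 (SE 0.58), with 3.01 in L002 and 2.51 in XY9274. Steap4, a metalloreductase, was at 53.7 ± 48.0 against 2.02 ± 3.80 CPM, and Lpar3, a receptor for lysophosphatidic acid, at 6.75 ± 4.14 against 0.282 ± 0.434 CPM. Fibrous 5 lay apart for both, with Steap4 at 0 and Lpar3 at 0.123 CPM. The receptor-type tyrosine phosphatases Ptprm and Ptprf were at 5.05 ± 3.29 against 0.521 ± 0.744 CPM and 12.99 ± 10.5 against 1.66 ± 2.59 CPM. Epb41l3, a membrane skeleton protein, was at 7.92 ± 6.70 against 0.677 ± 0.758 CPM. Rpap1, a partner of RNA polymerase II, had 1.48 (SE 0.40), and Zpr1, a zinc finger protein gene, 0.75 (SE 0.22). DESeq2 gave Mrc2 an adjusted p of 4.51e-09, Dst 2.56e-06, Lamb1 3.34e-06 and Zpr1 0.103.

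Among the 12 genes with lower values in fibrous libraries, Igkc (chromosome 6, 70726435 to 70726966), the immunoglobulin kappa constant region, had a log2 fold change of -3.53 (SE 1.01), with 7035 CPM in bone 5 and 233 in bone 6. In bone 1 Igkc was at 7.29 CPM, below the fibrous libraries, which lay between 7.97 and 264 CPM. Fgr, a Src family kinase of myeloid cells, had -2.04 (SE 0.53), and Trem3, a myeloid receptor, -2.02 (SE 0.61). Osm, the cytokine oncostatin M, was at 25.2 ± 16.6 against 105 ± 92.3 CPM, a log2 fold change of -2.00 (SE 0.57). Mgst2, a microsomal glutathione transferase, had -2.30 (SE 0.59), Calcrl, a receptor for adrenomedullin and calcitonin gene-related peptide, -1.53 (SE 0.48), and Hsd11b1, which regenerates active glucocorticoid, -1.55 (SE 0.49). The others were Evi2a (-1.72, SE 0.51), Emd, which encodes emerin of the nuclear envelope (-0.84, SE 0.25), Cstf2t, a factor of mRNA 3' end cleavage (-0.82, SE 0.26), Ethe1, a mitochondrial sulfur enzyme (-0.80, SE 0.25), and Vps26a of the retromer (-0.49, SE 0.15).

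Adgrf5 (ENSMUSG00000056492, chromosome 17, 43360451 to 43459557, plus strand), an adhesion G protein-coupled receptor, was at 10.2 ± 7.45 CPM in fibrous and 0.415 ± 0.877 CPM in bone libraries (log2 fold change 5.84, SE 1.63; adjusted p = 0.873). Its CPM was 0.0781, 23.0, 11.5, 14.6, 3.69, 8.07 and 10.6 in fibrous 1 to 7, and between 0 and 2.20 in the bone libraries. DESeq2 gave an adjusted p of 3.18e-04. The difference in mean log2(CPM + 1) was 2.69 (2.81 in L002, 2.52 in XY9274), with an exact permutation p of 0.00408 (adjusted p = 0.0408 over 10 measures), and 0.00661 (adjusted p = 0.0595) when libraries were exchanged only within their series. With 1 library left out it did not pass without bone 2, bone 3, bone 4, bone 5, fibrous 2, fibrous 3, fibrous 4, fibrous 6 or fibrous 7 (adjusted p = 0.0568, 0.0694, 0.0694, 0.0694, 0.0758, 0.0758, 0.0758, 0.0649 and 0.0649). Of the 13 tested adhesion GPCR genes, 4 passed 0.05 adjusted over the list alone and 0 over all genes. These were Adgrf5, Adgrg2 (3.36 ± 3.06 against 0.0965 ± 0.206 CPM), Adgra2 (2.82 ± 2.44 against 0.210 ± 0.455 CPM) and, with lower values in fibrous libraries, Adgrl4 (0.562 ± 1.36 against 9.99 ± 10.6 CPM). The list was chosen from memory of this study, so its counts are not independent evidence, and camera gave it an adjusted p of 0.114.

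Of the 36 lists tested, 19 passed with the preset correlation, 14 with higher and 5 with lower values in fibrous libraries. With an estimated correlation 0 passed (smallest adjusted p = 0.556), and 0 passed by fry (smallest adjusted p = 0.265), while the median estimated correlation within a list was 0.488. Over all lists, 8 list members passed 0.05 adjusted over the list alone and 0 over all genes. Without the 5 libraries low in Lepr, a setting chosen after seeing the data, 19 lists passed, but the pan-leukocyte, neutrophil, monocyte and chondrocyte lists did not (adjusted p = 0.170, 0.157, 0.713 and 0.246). The count was 10 with erythroid and pan-leukocyte scores as covariates, also chosen after seeing the data, and 11 in the L002 series alone. The lists that did not pass under these settings are given below with their p.

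The bone lineage lists had higher values in fibrous libraries. All 20 tested osteoblast genes had a fold change above 0, with a median of 1.00 (0.67 in L002, 1.78 in XY9274; adjusted p = 4.31e-07 preset and 0.556 with an estimated correlation). Examples were Alpl, the alkaline phosphatase of mineralising cells (1.27, SE 0.78), Spp1, which encodes osteopontin (0.87, SE 0.50), and Cthrc1, a collagen-associated secreted protein (1.12, SE 0.59). The 6 osteocyte genes had a median of 1.20 (1.00 in L002, 1.78 in XY9274; adjusted p = 0.00539 preset, 0.556 estimated, 0.0742 in L002 alone and 0.0887 with both scores). Phex, a peptidase that regulates phosphate, passed over the list alone (5.85 ± 4.61 against 0.979 ± 1.87 CPM; adjusted p = 0.0451), beside Dmp1, a matrix protein of osteocytes (1.10, SE 1.22), and Irx5 (1.30, SE 1.06). The osteocyte score differed by 2.39 between groups (exact permutation p = 0.00816, adjusted p = 0.0408; within series 0.0119, adjusted p = 0.0595). With 1 library left out the osteocyte score did not pass without bone 2 to 5 (adjusted p = 0.0568, 0.0694, 0.0694 and 0.0694), nor without fibrous 1, 2, 3, 4, 6 or 7 (adjusted p = 0.0649, 0.0758, 0.0758, 0.0758, 0.0649 and 0.0649). Without bone 1 the list medians were 1.64 for osteoblast and 2.20 for osteocyte genes, and without bone 4 the osteocyte median was 2.60. The osteoblast score was 7.44 ± 1.02 in fibrous and 5.53 ± 1.93 in bone libraries (exact permutation p = 0.0513, adjusted p = 0.1501). Of the 10 measures tested in this way, 2 passed, Adgrf5 and the osteocyte score.

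Collagen matrix and its enzymes followed the same direction. Some lists share members, so their directions are not independent. Col1a1, Col1a2 and Cthrc1 are in both the osteoblast and the fibrillar matrix list, and Phex is in both the osteoblast and the osteocyte list. In the fibrillar matrix list 22 of 24 genes had a fold change above 0, with a median of 1.06 (0.51 in L002, 2.09 in XY9274; adjusted p = 3.76e-07 preset and 0.556 estimated). Its score per library did not pass (exact permutation p = 0.0600, adjusted p = 0.1501). Fbn1, which encodes fibrillin, had 3.43 (SE 1.35), and Ogn, a small leucine-rich proteoglycan gene, 2.33 (SE 0.87), while Col5a3, a type V collagen chain, was at 13.8 ± 15.8 against 3.42 ± 6.16 CPM. Collagen processing genes had a median of 0.83 (0.27 in L002, 1.93 in XY9274; adjusted p = 4.32e-04 preset, 0.556 estimated, 0.0808 in L002 alone and 0.0888 with both scores), with P4ha3, a prolyl hydroxylase subunit, at 15.3 ± 13.6 against 3.25 ± 4.64 CPM, and log2 fold changes for Loxl1, a lysyl oxidase, of 2.04 (SE 1.15), P3h1 of 1.29 (SE 0.69) and Bmp1, the procollagen C-proteinase, of 1.10 (SE 0.59). Matrix proteases and inhibitors had a median of 1.30 (0.91 in L002, 1.58 in XY9274; adjusted p = 1.81e-05 preset and 0.556 estimated), with the inhibitor Timp1 at 1.06 (SE 0.50) and the plasminogen activator Plat at 12.7 ± 13.3 against 1.04 ± 1.90 CPM. Contractile myofibroblast genes had a median of 0.89 (0.66 in L002, 1.42 in XY9274; adjusted p = 0.00121 preset, 0.556 estimated and 0.280 without the 3 Lin-named libraries), with Acta2, smooth muscle actin, at 1.65 (SE 0.87), Tpm1 at 0.76 (SE 0.30) and Lrrc15 at 4.60 ± 5.14 against 0.516 ± 0.703 CPM. The universal fibroblast list had 0.72 (0.69 in L002, 1.26 in XY9274; adjusted p = 0.00992 preset, 0.556 estimated, 0.0730 in L002 alone and 0.0966 without bone 6), with Fbln1, a matrix glycoprotein gene, at 2.16 (SE 1.05) and Dpt, which encodes dermatopontin, at 3.42 ± 2.58 against 0.103 ± 0.168 CPM. Without bone 1 the medians were 1.88 for fibrillar matrix, 1.69 for collagen processing, 2.04 for proteases and inhibitors and 1.46 for universal fibroblast genes. The last was 1.22 without bone 2, 1.35 without bone 5 and 0.39 without fibrous 2.

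Marrow stromal genes had a median log2 fold change of 1.88, with all 21 above 0 (2.38 in L002, 0.64 in XY9274; adjusted p = 6.89e-04 preset, 0.561 estimated and 0.0888 with both scores), and 1.23 without fibrous 2. The marrow stromal score per library did not pass (exact permutation p = 0.155, adjusted p = 0.258). Apoe, an apolipoprotein, had 1.41 (SE 0.69) and Gas6, a ligand of TAM receptors, 2.42 (SE 1.37). Angpt1, a ligand of the Tie2 receptor, was at 5.15 ± 2.98 against 3.48 ± 6.11 CPM and had a log2 fold change of -0.95 in the XY9274 series. The tendon and ligament list had 0.81 (0.16 in L002, 2.92 in XY9274; adjusted p = 0.0222 preset, 0.556 estimated, 0.258 in L002 alone, 0.129 by DESeq2 and 0.0596 with both scores), 1.51 without bone 1 and 0.44 without fibrous 7 (adjusted p = 0.0960), with Tnc, which encodes tenascin C, at 1.56 (SE 1.11). The chondrocyte list had 0.30 (adjusted p = 0.00539 preset, 0.604 estimated, 0.114 without fibrous 7 and 0.190 without bone 6), with -0.76 in the L002 and 3.37 in the XY9274 series. Its members Prg4, the lubricin gene, and Sox9, the cartilage transcription factor, had 1.46 (SE 1.29) and 0.72 (SE 1.08), and Sox9 had -0.31 in L002. The chondrocyte median was 1.02, 0.55, 0.0621, 0.0380, -0.12 and -0.23 without bone 1 to 6, 0.60 without fibrous 5 and 0.0567 without fibrous 7. The list did not pass in L002 alone, without the Lin-named libraries, with the 3-level name factor, by DESeq2 or with both scores (adjusted p = 0.907, 0.154, 0.0769, 0.366 and 0.0587). Its median was -0.13 without the libraries low in Lepr and -0.0927 with the pan-leukocyte score.

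Among signalling lists, TGF-beta had a median of 0.96 (0.46 in L002, 0.88 in XY9274; adjusted p = 0.00162 preset and 0.556 estimated). BMP had 1.22 (0.79 and 1.97; adjusted p = 0.00539 and 0.561), Wnt 1.12 (0.39 and 1.92; adjusted p = 0.00539 and 0.556) and Hedgehog and Notch 0.97 (1.12 and 0.97; adjusted p = 0.0218 and 0.556). Hedgehog and Notch did not pass without fibrous 2, fibrous 6 or fibrous 7 (adjusted p = 0.0531, 0.0582 and 0.0505). In L002 alone BMP, Wnt and Hedgehog and Notch did not pass (adjusted p = 0.221, 0.208 and 0.212), and with both scores BMP and Hedgehog and Notch did not (adjusted p = 0.118 and 0.225). Hedgehog and Notch did not pass with the 3-level name factor, the stricter filter or the pan-leukocyte score either (adjusted p = 0.158, 0.189 and 0.0670). Medians were 1.49 for TGF-beta and 1.89 for Wnt without bone 1, and 1.54 for Hedgehog and Notch without bone 2. Acvr1, a type I receptor for BMP ligands, was at 5.87 ± 4.52 against 0.334 ± 0.431 CPM, and the BMP target Id3 had 1.44 (SE 0.53). Tgfbr2 had 1.04 (SE 0.60), Ccn2, a TGF-beta target, 1.48 (SE 0.96), and Frzb, a secreted Wnt antagonist, 2.11 (SE 1.05). Wnt5a was at 4.04 ± 5.05 against 0.610 ± 0.737 CPM and Gli3 at 3.31 ± 3.28 against 0.491 ± 0.693 CPM.

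Lists with lower values in fibrous libraries were of blood cells and of general cell functions. The neutrophil list had a median of -1.81 with all 11 genes below 0 (-1.91 in L002, -1.78 in XY9274; adjusted p = 3.63e-06 preset, 0.556 estimated, 0.0670 with the pan-leukocyte score and 0.165 with both scores), with S100a9 at -2.22 (SE 0.82) and Camp, the cathelicidin gene, at -2.29 (SE 0.85). The pan-leukocyte list had -1.56 (-1.57 in L002, -1.56 in XY9274; adjusted p = 1.11e-04 preset, 0.556 estimated, 0.163 with its own score and 0.255 with both scores), with Cd52 at -2.07 (SE 0.77), Tyrobp at -2.01 (SE 0.80) and Rac2 at -0.93 (SE 0.39). The monocyte and macrophage list had -1.04 (-0.62 in L002, -1.72 in XY9274; adjusted p = 0.0367 preset and 0.565 estimated), with Lyz2, lysozyme, at -1.93 (SE 0.73). It did not pass without fibrous 1, fibrous 4, fibrous 7, bone 2, bone 3 or bone 5 (adjusted p = 0.0900, 0.0997, 0.173, 0.148, 0.417 and 0.221), and its median was -0.68 without fibrous 7. Nor did it pass in L002 alone, without the Lin-named libraries, with the 3-level name factor, the stricter filter, DESeq2 size factors or upper-quartile factors (adjusted p = 0.528, 0.175, 0.201, 0.106, 0.0629 and 0.0533). With the erythroid, the pan-leukocyte and both scores its adjusted p was 0.0612, 0.810 and 0.568, and with both scores its median turned to 0.32. All 33 ribosomal protein genes were below 0, with a median of -0.46 (-0.66 in L002, -0.17 in XY9274; adjusted p = 5.95e-10 preset, 0.556 estimated and 0.191 in XY9274 alone), Rpl32 at -0.67 (SE 0.33) and Rpl23 at -0.44 (SE 0.21). Oxidative phosphorylation had -0.32 with 17 of 18 genes below 0 (-0.43 in L002, -0.22 in XY9274, with adjusted p = 1.34e-04 preset, 0.556 estimated, 0.0800 without the Lin-named libraries and 0.0840 in XY9274 alone), with the cytochrome oxidase genes Cox7a2 at -0.63 (SE 0.29) and Cox4i1 at -0.57 (SE 0.28). The highest ribosomal scores were in bone 3 and bone 4 (9.53 and 9.59), and the lowest was in bone 5 (7.66). Oxidative phosphorylation scores were also highest in bone 3 and bone 4 (9.08 and 9.19) and lowest in bone 5 (7.77).

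**Figure D2:**
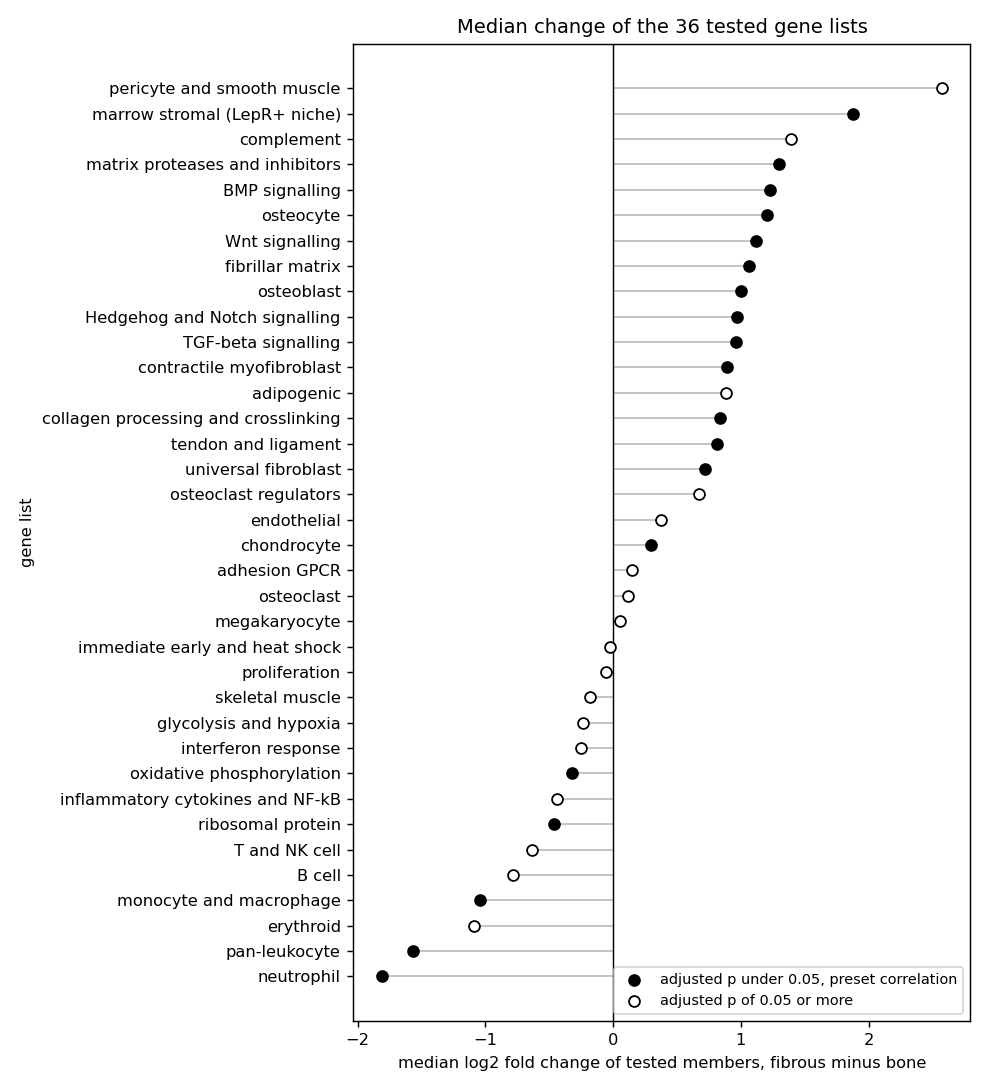
Median log2 fold change, fibrous minus bone, of the tested members of each of the 36 lists, with the list on the y axis. Filled points passed camera with the preset correlation and open points did not. The neutrophil list lies at -1.81 and the fibrillar matrix list at 1.06, and 0 lists passed with an estimated correlation.

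The other 17 lists did not pass, and no direction is given for them. Adjusted p with the preset correlation was 0.0574 for B cell, 0.0578 for pericyte and smooth muscle, 0.210 for erythroid, 0.210 for osteoclast regulators, 0.244 for adipogenic, 0.290 for glycolysis and hypoxia, 0.358 for complement and 0.358 for megakaryocyte. It was 0.364 for immediate early and heat shock, 0.417 for proliferation, 0.417 for T and NK cell, 0.542 for interferon response, 0.564 for inflammatory cytokines and NF-kB, 0.664 for osteoclast, 0.846 for endothelial and 0.846 for skeletal muscle, beside the adhesion GPCR list. The mitochondrially encoded, Schwann and mast cell lists had fewer than 3 tested members and were not tested. The median, the mean and the test differed in sign for the interferon response, proliferation, immediate early and heat shock, megakaryocyte, osteoclast and endothelial lists. Within the B cell list Jchain, the joining chain of secreted antibodies (13.2 ± 34.5 against 347 ± 734 CPM; adjusted p = 0.0156), and Igkc (adjusted p = 0.0184) passed over the list alone, as did Nkg7, a cytotoxic granule gene, in the T and NK cell list (-2.02, SE 0.72; adjusted p = 0.0450). Jchain was at 91.4 CPM in fibrous 7 and at 0.246 CPM or less in the other fibrous libraries. It was at 1842 CPM in bone 5 and between 0 and 133 CPM in the other bone libraries. Cxcl10, an interferon-induced chemokine, was at 3.36 ± 2.52 against 1.54 ± 3.78 CPM, with a log2 fold change of -0.59 in XY9274, and Lcn2, a siderophore-binding protein of neutrophils, had -1.77 (SE 0.78). The bone mean of Cxcl10 rests on bone 5, with 0 CPM in each other bone library. Pparg, the adipogenic regulator, was at 10.4 ± 13.7 against 1.07 ± 1.67 CPM, and Tnfsf11, the osteoclast-inducing ligand, at 8.44 ± 6.45 against 1.26 ± 1.82 CPM. Log2 fold changes of further members were 2.83 for Hspa1b (SE 0.94), -1.63 for Hbb-bs (SE 0.90), -0.35 for Pgk1 (SE 0.23) and -0.40 for Cdk1 (SE 0.20). Others turned sign under some settings. Pf4, a platelet chemokine, had 0.68 (SE 1.30), but -0.70 in XY9274, -1.56 with limma-voom and a Pf4 log2 fold change of -8e-04 without fibrous 5. Mmp9 had -0.71 (SE 0.50), with a Mmp9 log2 fold change of 0.0366 without the libraries low in Lepr. Mcm4 had 0.47 (SE 0.28), with -0.21 in XY9274 and a Mcm4 log2 fold change of -0.0454 without the libraries low in Lepr. Pecam1, at 6.80 ± 12.8 against 10.1 ± 16.6 CPM, had -2.78 (SE 1.29), with 0.0107 in XY9274, 2.64 with limma-voom, 0.13 with the pan-leukocyte score and 0.36 with both scores. Ighm had -1.73 (SE 0.82), with an Ighm log2 fold change of 0.0805 with the pan-leukocyte score and 0.0801 with both.

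**Figure D3:**
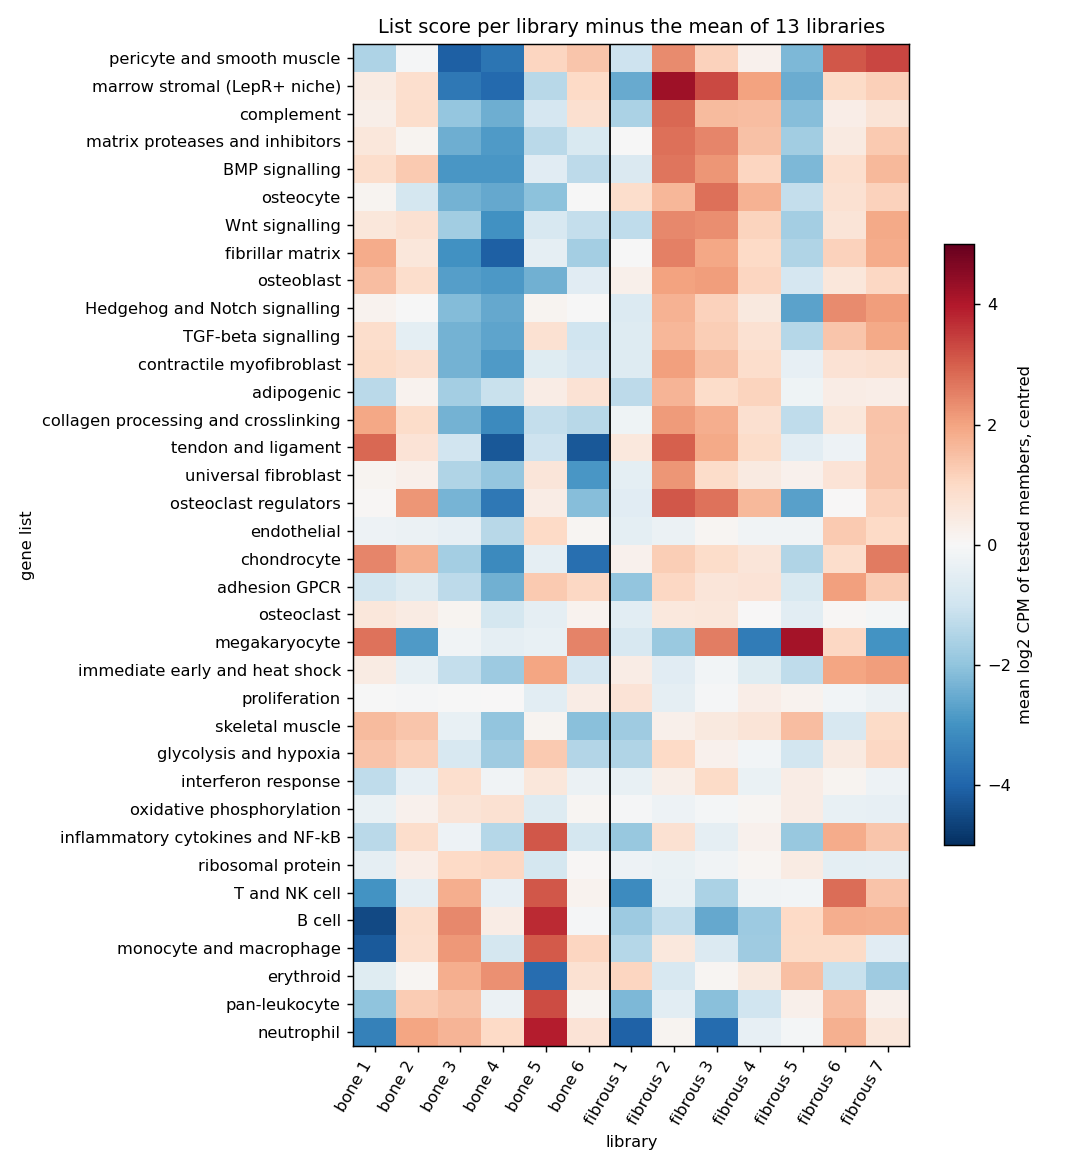
Score of each tested list (mean log2 CPM of its tested members, centred on the 13 libraries) on the y axis, for each library on the x axis, with bone to the left of the line and fibrous to the right. Red is above and blue below the mean of the list. Bone 3 and bone 4 have the 2 lowest scores of the marrow stromal, fibrillar matrix, osteoblast and osteocyte lists, with haemoglobin at 27.9% and 35.3% of their counts.

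Within the L002 series (4 bone and 5 fibrous libraries) edgeR called 0 genes (648 at an unadjusted p under 0.05), DESeq2 139 and limma-voom 1. That gene, 4833407H14Rik, named after its values were seen, was between 3.65 and 4.19 CPM in the L002 bone and between 0 and 0.0616 CPM in the L002 fibrous libraries. Over both series 4833407H14Rik was at 2.81 ± 1.73 CPM in bone and 0.158 ± 0.343 CPM in fibrous libraries. The contrast was thus smaller with the XY9274 libraries included. Within XY9274 (2 and 2 libraries) edgeR called 0 (562 at an unadjusted p under 0.05), DESeq2 226 and limma-voom 0. Mrc2 was at 5.49 and 11.2 CPM in the XY9274 bone libraries, at 36.9 and 56.7 CPM in the XY9274 fibrous libraries, at 0.201 CPM or less in the L002 bone and between 5.78 and 55.1 CPM in the L002 fibrous libraries. For the difference between the 2 series in the fibrous against bone contrast, edgeR called 0 genes (292 at an unadjusted p under 0.05), DESeq2 25 and limma-voom 0. Of the lists, 11 passed in L002 and 23 in XY9274 with the preset correlation.

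Between the name series, the immediate early and heat shock list had a median log2 difference of 1.66, XY9274 minus L002 (adjusted p = 7.11e-05 preset and 0.837 with an estimated correlation). Its score was 8.21, 8.33 and 8.23 in fibrous 6, fibrous 7 and bone 5. In bone 6, also of XY9274, it was 5.38, within the L002 range of 4.41 to 6.63. Blood cell lists differed as well, with -2.64 for erythroid (adjusted p = 1.12e-04 preset and 0.837 estimated), 1.75 for neutrophil (adjusted p = 0.0293 and 0.837), 1.36 for pan-leukocyte (adjusted p = 0.0444 and 0.837) and 1.42 for B cell genes (adjusted p = 0.0493 and 0.837). The erythroid score of bone 6, 12.4, also lay within the L002 range of 10.8 to 13.9. Ribosomal protein genes had -0.69 (adjusted p = 4.21e-10 and 0.837), oxidative phosphorylation -0.62 (adjusted p = 3.43e-05 and 0.837), proliferation -0.33 (adjusted p = 0.0157 and 0.837), osteoblast -1.13 (adjusted p = 0.0493 and 0.934) and adhesion GPCR genes 1.60 (adjusted p = 0.0293 and 0.837). Of the 36 lists, these 10 passed with the preset and 0 with the estimated correlation. With group as a term, 287 genes changed, of which 251 rose and 36 fell in XY9274 relative to L002 (13294 tested; 9 and 4 libraries; 2981 at an unadjusted p under 0.05). Genes induced within minutes of cell handling or stress were among those that rose: Fosb, an AP-1 subunit (log2 difference 4.61, adjusted p = 0.0295), Nr4a1, an immediate early nuclear receptor (4.05, adjusted p = 0.00847), Hspa1b, a heat shock protein gene (4.16, adjusted p = 0.0353), Klf6 (1.66, adjusted p = 0.0497) and Zfp36 (1.61, adjusted p = 0.0404). These are 5 of the 19 genes of the immediate early and heat shock list. Of the 12 inflammatory and NF-kB genes, Tnfaip3, an inhibitor of NF-kB, rose by 4.20 (adjusted p = 0.0302) and Nfkbiz by 3.03 (adjusted p = 0.0426). Nkg7 rose by 3.41 (adjusted p = 0.0339) and Fasn, fatty acid synthase, by 3.01 (adjusted p = 0.0360). The smallest adjusted p of the genes that rose was that of Wdr74, which is in none of the fixed lists (adjusted p = 3.14e-06). Its mean was 1.05 CPM in L002 and 61.2 CPM in XY9274. Metrn, also in no list, had means of 1.77 and 26.6 CPM. Brms1, a corepressor subunit gene, fell from a mean of 61.2 to 0.0142 CPM (adjusted p = 8.50e-07), B4gat1, a glucuronyltransferase gene, from 36.1 to 0.00475 CPM (adjusted p = 2.87e-04) and Fam220a from 135.5 to 0.622 CPM (adjusted p = 0.0142). Both Brms1 and B4gat1 lay under the limit of a count of 0 in every XY9274 library. Exons of other genes cover 79.0%, 85.3% and 61.0% of the exonic length of Brms1, B4gat1 and Fam220a. A difference in counting was therefore not told apart from one in expression for these genes. DESeq2 called 1982 genes and limma-voom 2864. The count was 55, 65 and 69 with the erythroid, the pan-leukocyte and both scores, 170 with upper-quartile factors, 32 without the 5 libraries low in Lepr, 87 without fibrous 6, 90 without bone 5, 137 without fibrous 7, 151 without fibrous 3, 179 without bone 4, 184 without fibrous 2, 191 without bone 3 and 470 without bone 1.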

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

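All tests of explanations in this part were chosen after the result was seen, and the counts over other splits of the libraries were planned.

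In 244 groups of values, 16 held a library far from the others of its group by Dixon's test, where chance gives about 12.2 (1 in 20). Values are log2(CPM + 1). Bone 6 was the highest bone library for Adgrf5 (1.68), Ebf3 (1.15), Ptprz1 (1.46), Timp4 (0.57) and Adgra2 (1.09). Bone 5 was the highest for Cxcl10 (3.36), Adgrg2 (0.60) and Mmp9 (10.93), bone 1 for Dpt (0.52) and bone 3 for Gli3 (1.52). Among the fibrous libraries, fibrous 5 was the lowest for Lpar3 (0.17), Steap4 (0), Zpr1 (5.63) and Ccn2 (5.39). Fibrous 6 was the highest for Adgrl4 (2.21) and fibrous 7 for Jchain (6.53).

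Lepr was near 0 in 5 libraries that the labels give as sorted for its protein. Shallow sequencing is argued against, because at the lowest CPM of the other libraries the smallest expected count in these 5 is 465. Dilution of stromal RNA by one factor would lower Lepr and osteoblast genes alike. Lepr lay further below the other libraries than the osteoblast list did, by a median of 3.03 on the log2 scale against a spread of 1.44 (interquartile range). The 5 libraries were chosen for low Lepr, so part of this gap is built in and the test cannot decide. Their marrow stromal scores, a list that includes Lepr, also lay lower, between -0.13 and 2.36 against 4.16 to 8.01 in the others. A different sort or label behind the Lin names stays open as a hypothesis: all 3 Lin-named libraries are among the 5 (2-sided Fisher's exact p = 0.0350, and 0.0476 within L002). The test treats libraries as independent, although bone 4 and fibrous 5 share name tokens with bone 2 and fibrous 2. Fibrous 1 and bone 5 are not Lin-named, but the name of fibrous 1 also lacks the token plus. Lepr lay between 46.7 and 804 CPM in the L002 libraries with plus in their name. No biological explanation was tested.

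Adgrf5 had a mean 2.69 higher in fibrous libraries on the log2(CPM + 1) scale. Its presence in one series alone is argued against, since the smaller of the within-series differences was 2.52. Endothelial cells as the source were tested over 5 markers past the filter, which left it open (median difference 0.559, interquartile range 1.11, where a median of at least 1.34, 50% of the Adgrf5 difference, was needed). A second test over all 13 list genes in the matrix, added after the first result and these values were seen, argues against it (median -0.0095, interquartile range 0.230), although many of these genes lie near the floor, and it stays open for fibrous 6 and 7, where Pecam1 was at 34.1 and 12.03 CPM, although Pecam1 was highest in bone 5 (43.1 CPM), where Adgrf5 was at 0. A larger share of Lepr-expressing cells cannot be told apart (Adgrf5 per Lepr differed by 2.05 on the log2 scale, exact permutation p = 0.0714 over 56 splits of 3 bone and 5 fibrous libraries), and a difference between the tissues stays open. The ratio was taken with a pseudocount of 1, above the Adgrf5 level of bone 1 and bone 2 (0.0394 and 0.0829 CPM). Its size and its p therefore depend on that pseudocount.

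The 36 genes lower in XY9274 included 9 (25%) with at least 25% of their exonic length under exons of another gene, against 676 of 13007 other tested genes (5.20%, Fisher's exact p = 7.55e-05). For the 251 genes higher in XY9274 it was 7 (2.79%, Fisher's exact p = 0.110). Brms1, B4gat1 and Fam220a, named above, were among the 9. A different treatment of overlapping genes in the counting of the name series may therefore account for part of the pattern, as a hypothesis, though most of these genes have no such overlap. Unequal erythroid and leukocyte RNA is argued against for these 36 genes only. With both scores as covariates the median ratio of their log2 differences was 0.883 (interquartile range 0.146). With both scores 12 of the 36 still passed, while the median went from -1.80 to -1.30 and the median SE from 0.273 to 0.280. The 251 genes higher in XY9274 were not tested in this way. With both scores 45 genes passed as higher in XY9274, and with the erythroid score 33, so unequal blood cell RNA stays open for the genes that rose.

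Splits of the libraries into groups of the same sizes, the real one included, gave as large a result in 20 of 100 for the DESeq2 count (169; highest other 3289) and in 20 of 100 for the lists called with the preset correlation (19; highest other 26). Chance cannot be excluded for these 2 counts. For the edgeR count (0; highest other 465) and L002 alone (0; highest other 828) it was 100 of 100, which a count of 0 gives in any case, so these cannot tell. For the name series it was 1 of 100 (287, with 6 as the highest other), the smallest share that 100 splits can give. Chance is therefore unlikely there but not excluded. The splits treat libraries as independent, although some share name tokens.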

How the results depend on the processing

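The settings that leave out low-Lepr libraries, add scores or the Lepr level as covariates or leave out erythroid genes, and all alternatives within each series, for the interaction and between series, were chosen after seeing the data. For fibrous against bone, edgeR called 0 genes under every setting run (636 at an unadjusted p under 0.05 with all libraries), with the smallest adjusted p from 0.0944 (without bone 5) upward, limma-voom called 0 (1151) and DESeq2 169. DESeq2 called 29 of the 98 named genes, 139 genes in L002 (limma-voom 1), 226 in XY9274 and 25 for the interaction. Lists called were 11 in L002 alone, 10 with erythroid and pan-leukocyte scores, 0 with an estimated correlation and 0 by fry. Between series, the count was 1982 by DESeq2, 2864 by limma-voom, 170 with upper-quartile factors, 32 without low-Lepr libraries, 55, 65 and 69 with the erythroid, the pan-leukocyte and both scores, and 87 (without fibrous 6) to 470 (without bone 1) with 1 library left out.

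Of 2893 values of named genes, 16 in 9 genes turned sign, and of 569 values of the 19 called lists, 6 in 2 lists. Of these list values 56 no longer passed, 4 of them with a turned sign. The cause was not tested. Only called lists were followed in this way, a limit set after sign changes of the others were seen. Tests of 2 explanations for the matrix and osteoblast lists were written down and then dropped without being run. In L002 alone Sox9 had -0.31 and the chondrocyte list -0.76. In XY9274 alone Angpt1 had -0.95, Cxcl10 -0.59, Pecam1 0.0107, Pf4 -0.70 and Mcm4 -0.21. With limma-voom Pecam1 had 2.64 and Pf4 -1.56. Without low-Lepr libraries the Mcm4 log2 fold change was -0.0454, the Mmp9 log2 fold change 0.0366 and that of the chondrocyte list -0.13. With the pan-leukocyte score the Ighm log2 fold change was 0.0805, Pecam1 0.13 and the chondrocyte list -0.0927, and with both scores Lepr had -0.27, Ighm 0.0801, Pecam1 0.36 and the monocyte list 0.32. With 1 library left out the Pf4 log2 fold change ran from -8e-04 to 1.24 and the chondrocyte list from -0.23 to 1.02. The 98 genes followed are part of the 158 named by the rule. The 12 genes filled in each direction were chosen for the same sign in both series, so their signs there were fixed in advance. Of all 158, 22 turned sign within a name series, and 16 of these were not followed, among them Comp (-0.39 in L002), Cd34 (-2.40 in XY9274), Fmod (-0.26 in L002), Il34 (-2.99 in XY9274), Tnfrsf11b (-0.71 in L002), Mcm3 (-0.29 in XY9274) and Ldha (0.24 in XY9274). Of the 17 lists not called, 13 turned the sign of their median in at least 1 of 30 settings.

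The median of all genes lay at 0.03, at 0.17 with limma-voom (0.24 in L002, 0.15 between series and -0.21 for the interaction), between series at 0.29 with no filter, 0.16 without bone 1 and -0.13 with upper-quartile factors, and at -0.10 in XY9274 alone. The stricter filter left no genes for XY9274 alone. No label pairs a fibrous with a bone library, since replicate numbers follow accession order and the shared name tokens lie within a group, so no paired analysis was run. In simulated data edgeR called 50.5% of genes changed 8-fold, so smaller differences than that would often be missed at this spread.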

Other observations

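All values here were picked out after the data were seen, and no explanation was tested for them. DESeq2 alone called 13 genes that the fixed lists hold, with edgeR adjusted p of 0.873 for each. Cd34, a sialomucin of progenitor and endothelial cells, had a DESeq2 log2 fold change of 7.26 (adjusted p = 0.00303) although its mean was 10.96 ± 26.8 CPM in bone and 7.82 ± 5.14 CPM in fibrous libraries, and its edgeR log2 fold change was -2.40 in XY9274. Its bone mean rests on bone 5, at 65.7 CPM, with 0.0414 CPM or less in each other bone library. It stood beside the adhesion GPCR genes Adgrf5, Adgra2 and Adgrg2, which DESeq2 placed at 5.92, 6.52 and 6.08, with bone means of 0.415, 0.210 and 0.0965 CPM. Phex and Ptprz1, both of the osteocyte list, had 4.63 (adjusted p = 0.00508) and 4.99 (adjusted p = 0.0383) by DESeq2, with bone means of 0.979 and 0.325 CPM. Igkc had -3.57 (adjusted p = 0.00571). The simulated data gave 264 unchanged genes called by DESeq2 over 4 sets, against 13 by edgeR.

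The first principal component held 30.6% of the variance, with bone 4, bone 3 and fibrous 5, the Lin-named libraries, at 198, 186 and 106, and fibrous 7 and fibrous 2 at -114 and -102. Kitl, a niche factor of marrow stromal cells, was at 95.5 CPM in fibrous 2 and at 0.201 CPM or less in bone 1, bone 3, bone 4, bone 5, fibrous 1 and fibrous 5.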
